A study of Mus musculus with 18 samples.

How the data were processed

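The series holds poly(A)-selected RNA sequencing of retinas from mice heterozygous for the P23H knock-in allele of Rho and from wildtype mice at 1, 3 and 6 months, with 3 libraries in each of 6 groups. Group and age were taken from the labels. Per the series text, the authors aligned paired reads with Bowtie2 2.1.0 to a UCSC transcript set and estimated gene levels with RSEM 1.2.15, and the submitters' processing notes name the mouse build mm9. How reads were assigned by strand is not stated, so genes that overlap on opposite strands, such as Fgf2 and Nudt6, and families with shared reads, such as crystallins and haemoglobins, are uncertain. The authors' deposited count file gives RSEM expected counts per gene and library for 24054 genes. In it 15.6% of values are not whole (tolerance 1e-06) and 3702 genes are 0 in every library. The authors' deposited CPM columns are a signal in CPM with TMM scaling, and in them the scaling factor enters a second time. The authors' deposited comparison tables hold 15122 genes and give a fold change, written as a ratio or as minus its inverse when lower. The same tables give the p-value and FDR of the authors' edgeR run, whose version is not stated, and the authors' stated rule for called genes is p under 0.05 and over 1.5-fold. The deposited tables of 9 comparisons were used only as comparison values, and 54 of the deposited columns were not used.

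Expected counts were rounded to whole numbers. Genes were kept with filterByExpr over the 6 groups, which left 15888 of 24054, and libraries were scaled with TMM. A model with a mean per group was fitted to all 18 libraries in edgeR 4.0.16 under R 4.3.3 with glmQLFit and tested with glmQLFTest, with 12 residual degrees of freedom. Tests are 2-sided and p-values were adjusted by Benjamini-Hochberg over the genes tested in each of 13 contrasts, with a threshold of 0.05 and no fold minimum. Log2 changes and standard errors come from the same fit. The contrasts are P23H against wildtype at each age and over all ages, each pair of ages within a genotype, and the differences of the genotype effect between ages. The labels give no batch, sex or litter, and no term was added for them. Choices of test, threshold, gene lists and the rule for named genes were made before the data were examined, apart from the alternatives and the named genes given below as added or chosen later.

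Gene lists numbered 31, with 539 different genes, of which 3 names were missing from the file. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, whose test asks whether a list moves in a direction and not whether it differs from other genes. Camera p-values were adjusted together over 186 tests. At a preset correlation 16, 18 and 17 lists passed at 1, 3 and 6 months, and 2, 5 and 5 of them passed with an estimated correlation. In the genotype comparisons at a single age, a list is described when its camera adjusted p is under 0.05, when at least as many of its tested members pass as do not, or when it is rod phototransduction, cone photoreceptor, endoplasmic reticulum chaperones and ERAD, PERK-ATF4-CHOP response, reactive gliosis, microglia and macrophage, retinal pigment epithelium or lens. In the age comparisons and the differences of effects only some of the lists that meet this rule are described, chosen after their values were seen, and the number of lists called is given. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list.

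Named genes follow a rule. Rho is named in each comparison. For each genotype comparison the rule takes the 6 largest rises and 6 largest falls among genes past the threshold whose 3 P23H and 3 wildtype libraries do not overlap in CPM and whose mean is at least 5 CPM in the higher group. For age comparisons and differences of effects it takes 4 and 4, with no overlap condition for differences. Predicted and sex-linked genes are passed over. In a described list the rule takes up to 4 members with the largest changes past the threshold at 1 CPM or more in the higher group, and up to 2 of the most abundant where none passes. Gnat1, Krt12, Pmel, Hbb-b1, Cryaa, Xist and Ddx3y in the account of the libraries and in the plots, and genes followed across ages in the age comparisons, were chosen after their values were seen.

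The totals of 16.3 to 21.8 M expected counts per library set the counting precision, and genes named in a comparison with 10 or fewer counts in all in a group are given with those counts. Alternatives were scaling by RLE, by upper quartile, by library size alone and by 56 inner retinal neuron genes (bipolar, amacrine, horizontal and ganglion cell lists), no filter beyond 1 count (20301 genes), at least 1 CPM in 3 libraries (15122 genes), DESeq2 1.42.0, limma with trend on the log2 deposited CPM, a block for replicate number, only the libraries compared, the authors' rule, an adjusted p with 1.5-fold, and leaving out each library. Added after seeing the data were terms for sex, for a lens score and for a cornea, muscle and sclera score, limma with the scaling factor used once, and trends on transcript GC content and on transcript length taken out through offsets. Replicate numbers were checked for pairing through correlations of library residuals. The pipeline was tested on simulated data with 200 of 15888 genes changed and a gene list shifted. The rates that follow hold for those data only. Genes changed 2-fold were recovered at 76.1, 61.2 and 71.6% at 1, 3 and 6 months, those changed 1.5-fold at 32.8, 31.3 and 23.9%, and 4.14, 4.35 and 2.63% of calls were false.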

Results

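RNA from retinas of 18 mouse samples was sequenced after poly(A) selection. The samples form 6 groups of 3 by genotype and age: mice heterozygous for the P23H knock-in allele of Rho and wildtype mice, each at 1, 3 and 6 months. The labels give each replicate as a separate sample, so a p-value here measures the spread between samples. The series title sets the question as a comparison of the P23H retina with wildtype at each age. Total expected counts lay between 16.3 and 21.8 M per library. In wildtype they were 21.3, 21.8 and 17.9 M at 1 month, 17.5, 19.1 and 16.9 M at 3 months and 19.0, 19.1 and 18.8 M at 6 months. In P23H they were 16.5, 16.7 and 16.3 M, 17.5, 17.4 and 17.5 M, and 17.9, 18.9 and 18.3 M at the same ages. Between 17550 and 18201 genes had a count in a library, and 15888 were tested. The 10 most counted genes took 3.46 to 10.3% of a library. Rho alone took 2.97 to 4.05% in wildtype and 0.571 to 2.11% in P23H. Changes below are log2 ratios ± standard error with n = 3 libraries per group, CPM values are TMM-scaled, and p-values are adjusted over the genes tested.

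The libraries also differed in ways the groups do not name. On principal component 1, which held 38.2% of the variance, all wildtype libraries scored between 6.71 and 56.69 and the 1-month P23H libraries between 5.32 and 6.4. P23H 3-month replicates 2 and 3 and the 6-month P23H libraries scored between -65.76 and -29.4, and P23H 3-month replicate 1 scored 0.68. A female pattern (Xist at 1940 CPM or more, Ddx3y at 0.425 CPM or less) was present in 5 of 9 P23H and 2 of 9 wildtype libraries, and no member of the sex-linked list passed the test in a genotype comparison. Cryaa, a crystallin of the lens, ranged from 12.5 to 19240 CPM across libraries. Krt12, a keratin of the corneal epithelium, was at 924 CPM in P23H 3-month replicate 3 and at 2.13 and 2.19 CPM in the other P23H libraries of that age. Hbb-b1, a haemoglobin chain whose reads are shared with its paralogs, was at 131, 103 and 57.4 CPM in the 6-month P23H libraries and at 30.7, 9.52 and 21.7 CPM in wildtype. Pmel, a melanosome protein, was at 329, 585 and 313 CPM in the 6-month P23H libraries and at 4.81, 23.1 and 79.4 CPM in wildtype.

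**Figure D1:**
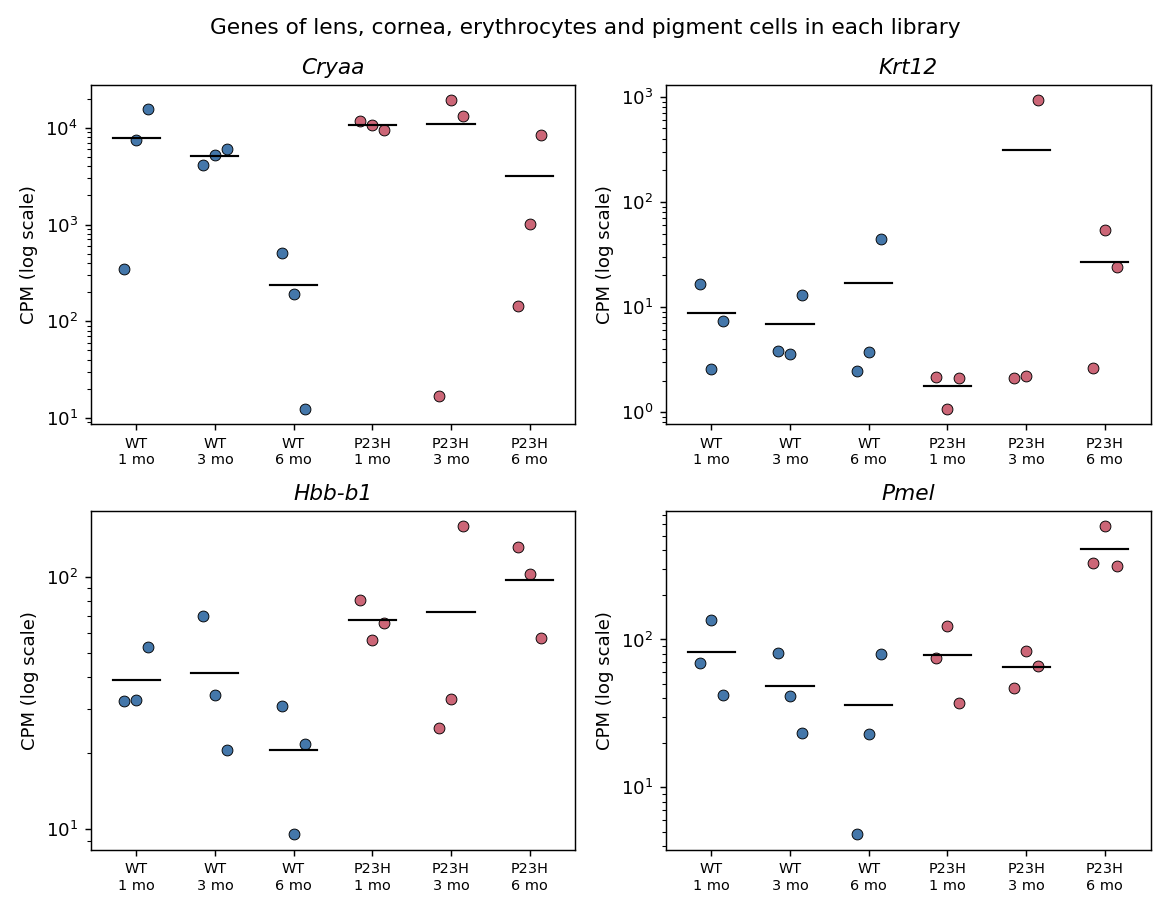
TMM-scaled CPM on log axes of the lens gene Cryaa, the cornea gene Krt12, the erythrocyte gene Hbb-b1 and the pigment cell gene Pmel, by genotype and age, with a point per library and a line at each group mean. Krt12 stands at 924 CPM in P23H 3-month replicate 3, and Cryaa spans 12.5 to 19240 CPM.

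At 1 month the P23H retina held less Rho transcript and more transcript of some stress and immediate early genes than wildtype. Rho, the rod visual pigment and the gene that carries the mutation, was at 39310 ± 6970 CPM (SD, n = 3) in wildtype and 20700 ± 575 CPM in P23H, a change of -0.93 ± 0.21 (adjusted p = 0.021, lower in 3 of 3 P23H libraries than in any wildtype library). That call ended without any of the 6 libraries but wildtype replicate 3: its adjusted p was 0.079, 0.0654 and 0.0597 without P23H replicates 1, 2 and 3, 0.1 and 0.0898 without wildtype replicates 1 and 2, and also 0.104 when libraries were scaled on inner retinal neurons. The range over the 13 alternatives run for this gene was 0.000198 to 0.104. The largest rises under the naming rule were in Edn2 (3.58 ± 0.33, adjusted p = 1.92e-05), an endothelin peptide that went from 4.83 to 58.1 CPM, Lad1 (3.48 ± 0.39), an anchoring filament protein, and Tnnt2 (3.29 ± 0.45), a cardiac-type troponin. Bcl3, a modulator of NF-kappa-B (2.98 ± 0.51), Egr4, a zinc finger transcription factor (2.74 ± 0.45), and Fgf2, a growth factor whose gene overlaps the antisense gene Nudt6 (2.63 ± 0.24), followed. The largest falls under that rule were in Glb1l3, a galactosidase-like gene (-2.94 ± 0.35, adjusted p = 0.000229, from 14.8 to 1.91 CPM), Dleu7 (-2.16 ± 0.26), Hdc, the enzyme that makes histamine (-1.62 ± 0.30), and Wisp1, a secreted matricellular protein (-1.36 ± 0.21). Col19a1 (-1.15 ± 0.25, adjusted p = 0.0161) and Traf3ip3 (-1.07 ± 0.20, adjusted p = 0.00709) completed the falls, and both calls ended when libraries were scaled on inner retinal neurons. The Col19a1 call also ended without P23H replicate 2 or 3.

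Of 16 immediate early genes, which neurons and glia switch on within minutes of a stimulus, 9 rose and none fell, with a median of 1.52 (camera adjusted p = 1.8e-18, and adjusted p = 0.00742 with an estimated correlation). Adjusted over the list alone, 11 rose. Fosb rose from 2.64 to 15.8 CPM (2.58 ± 0.20, adjusted p = 4.43e-06), and Egr3 (2.53 ± 0.42), Fosl2 (2.13 ± 0.40) and Junb (1.66 ± 0.18) rose with it. Of 16 genes of stress and survival cytokine signalling, 7 rose, 10 when adjusted over the list alone, with a median of 0.79 (camera adjusted p = 3.35e-22, and adjusted p = 0.000955 with an estimated correlation). They included Edn2, Bcl3, Fgf2 and the transcription factor Cebpd (2.49 ± 0.28, adjusted p = 0.000138). These were the only 2 of the 16 lists with a camera adjusted p under 0.05 at 1 month that kept the call with an estimated correlation.

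Some genes of the reactive gliosis, complement, interferon and microglia lists were higher as well, while most members did not pass and no camera call on these 4 lists held with an estimated correlation. In reactive gliosis 4 of 18 rose (6 adjusted over the list alone, median 0.82, camera adjusted p = 2.13e-06, and adjusted p = 0.126 with an estimated correlation). They included Osmr, a cytokine receptor chain (1.57 ± 0.22). Gfap, the glial intermediate filament, rose by 1.29 ± 0.35 (adjusted p = 0.047), a call that ended when any of the 6 libraries was left out. In complement 5 of 16 rose (7 adjusted over the list alone, median 0.67, camera adjusted p = 1.39e-06, and adjusted p = 0.228 with an estimated correlation). C4b went from 18.5 to 110 CPM (2.56 ± 0.37, adjusted p = 0.00111). In interferon response and antigen presentation 10 of 25 rose (12 adjusted over the list alone, median 0.68, camera adjusted p = 7.42e-12, and adjusted p = 0.181 with an estimated correlation). They included the membrane tether Bst2 (1.56 ± 0.29) and the guanylate-binding protein Gbp2 (1.29 ± 0.25). In microglia and macrophage 3 of 23 rose (10 adjusted over the list alone, median 0.71, camera adjusted p = 2.16e-06, and adjusted p = 0.328 with an estimated correlation). They included the purinergic receptor P2ry12 (0.94 ± 0.18, adjusted p = 0.00761). Beside these lists, the erythrocyte list had a median of 0.95 with 0 of 7 members past the test (camera adjusted p = 0.0737, and adjusted p = 0.644 with an estimated correlation), and 1 member passed with a term for sex (camera adjusted p = 0.00447). Hbb-b1 was at 81.2, 56.4 and 65.5 CPM in P23H and at 32.1, 32.4 and 52.7 CPM in wildtype. Without P23H replicates 1, 2 and 3 and wildtype replicates 1 and 2 in turn, the interferon count was 5, 5, 6, 5 and 3. Without P23H replicate 1 or 2 or wildtype replicate 1 or 2, gliosis gave 2 each time, microglia 1 each time, and complement 1, 2, 2 and 1.

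In rod phototransduction 9 of 20 genes fell and none rose (13 adjusted over the list alone, median -0.47, camera adjusted p = 4.06e-10, and adjusted p = 0.185 with an estimated correlation). Besides Rho they included Slc24a1, the rod sodium-calcium exchanger (-0.81 ± 0.17), Gnb1, the rod transducin beta subunit (-0.76 ± 0.15), and Cngb1, a channel subunit (-0.72 ± 0.14). The Slc24a1 call ended without P23H replicate 1 or 2 or wildtype replicate 1 or 2, and the Cngb1 call without P23H replicate 2 or wildtype replicate 1 or 2. In outer segment and photoreceptor cilium 6 of 23 fell (12 adjusted over the list alone, median -0.34, camera adjusted p = 4.44e-06, and adjusted p = 0.311 with an estimated correlation). They included the disc proteins Rom1 (-0.85 ± 0.14, adjusted p = 0.00298) and Prph2 (-0.74 ± 0.14). Of 15 photoreceptor transcription factors 2 fell, Mef2c (-0.83 ± 0.11, adjusted p = 0.000522) and Nrl, which specifies rods (-0.77 ± 0.15). That list's median was -0.14, and 0.04 with inner neuron scaling (camera adjusted p = 0.0276, and adjusted p = 0.364 with an estimated correlation). Of 17 photoreceptor synapse genes 3 fell, among them the glutamate transporter Slc17a7 (-0.64 ± 0.12, not past without wildtype replicate 1 or 2), with a median of -0.14 that turned to 0.02 with inner neuron scaling (camera adjusted p = 0.0108, and adjusted p = 0.314 with an estimated correlation). With inner neuron scaling no rod, outer segment or synapse gene passed, and Nrl did not pass either. Leaving out P23H replicates 1, 2 and 3 and wildtype replicates 1 and 2 in turn left 3, 2, 4, 1 and 2 rod genes. Leaving out wildtype replicate 3 gave 11 outer segment and 6 synapse genes, and leaving out P23H replicate 3, wildtype replicate 1 or wildtype replicate 2 gave 1, 0 and 0 synapse genes.

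The cone list had 1 of 12 genes higher, Gnb3, a cone transducin beta subunit that went from 274 to 660 CPM (1.27 ± 0.15, adjusted p = 0.000285). Its median was 0.20 (camera adjusted p = 0.0238, and adjusted p = 0.663 with an estimated correlation). In endoplasmic reticulum chaperones and ERAD 1 of 25 rose, Xbp1 (0.66 ± 0.13, adjusted p = 0.0105), an unfolded protein response factor whose call ended without wildtype replicate 1 or 2, while 7 genes of the list passed without wildtype replicate 3. In the PERK-ATF4-CHOP response 2 of 17 rose, Atf3 (1.58 ± 0.15, adjusted p = 3.19e-05) and Atf4 (0.42 ± 0.12, adjusted p = 0.0473), with a median of 0.03 (camera adjusted p = 0.0188, and adjusted p = 0.364 with an estimated correlation). Of that list 1 gene passed when any library but wildtype replicate 3 was left out. Small medians with a camera call also stood in amacrine cell (-0.33, 1 of 17 lower, adjusted p = 0.516 with an estimated correlation), retinal ganglion cell (-0.35, 0 of 13, adjusted p = 0.72 with an estimated correlation), oxidative phosphorylation (-0.06, 2 of 44 lower, adjusted p = 0.82 with an estimated correlation) and glycolysis and lactate (-0.09, 1 of 21 lower, adjusted p = 0.696 with an estimated correlation). The oxidative phosphorylation median turned positive with library size alone and with inner neuron scaling, and the glycolysis median with inner neuron scaling. Without wildtype replicate 3 these counts were 8 amacrine, 0 ganglion cell, 8 oxidative phosphorylation and 7 glycolysis genes, and without wildtype replicate 1 or 2 all were 0. Without P23H replicates 1 and 2 they were 0 and 0 amacrine, 1 and 1 oxidative phosphorylation and 0 and 0 glycolysis genes, and without P23H replicate 3 there were 3 amacrine and 0 glycolysis genes. No member passed in retinal pigment epithelium (median -0.19, 0.04 with inner neuron scaling) or in lens (median 0.37), where Ttr was at 0.19 ± 0.60 and Cryaa at 0.46 ± 1.57.

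At 1 month 794 genes passed (425 higher, 369 lower), and 3696 had an unadjusted p under 0.05. It was 297, 274 and 499 without P23H replicates 1, 2 and 3, and 185, 212 and 3163 without wildtype replicates 1, 2 and 3. Inner neuron scaling gave 255 genes (238 higher, 17 lower), library size alone 556 higher and 160 lower, and DESeq2 1597. Limma on the deposited CPM gave 1443 (420 and 1023), with its factor used once 904 (490 and 414), and only the libraries compared 231.

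**Figure D2:**
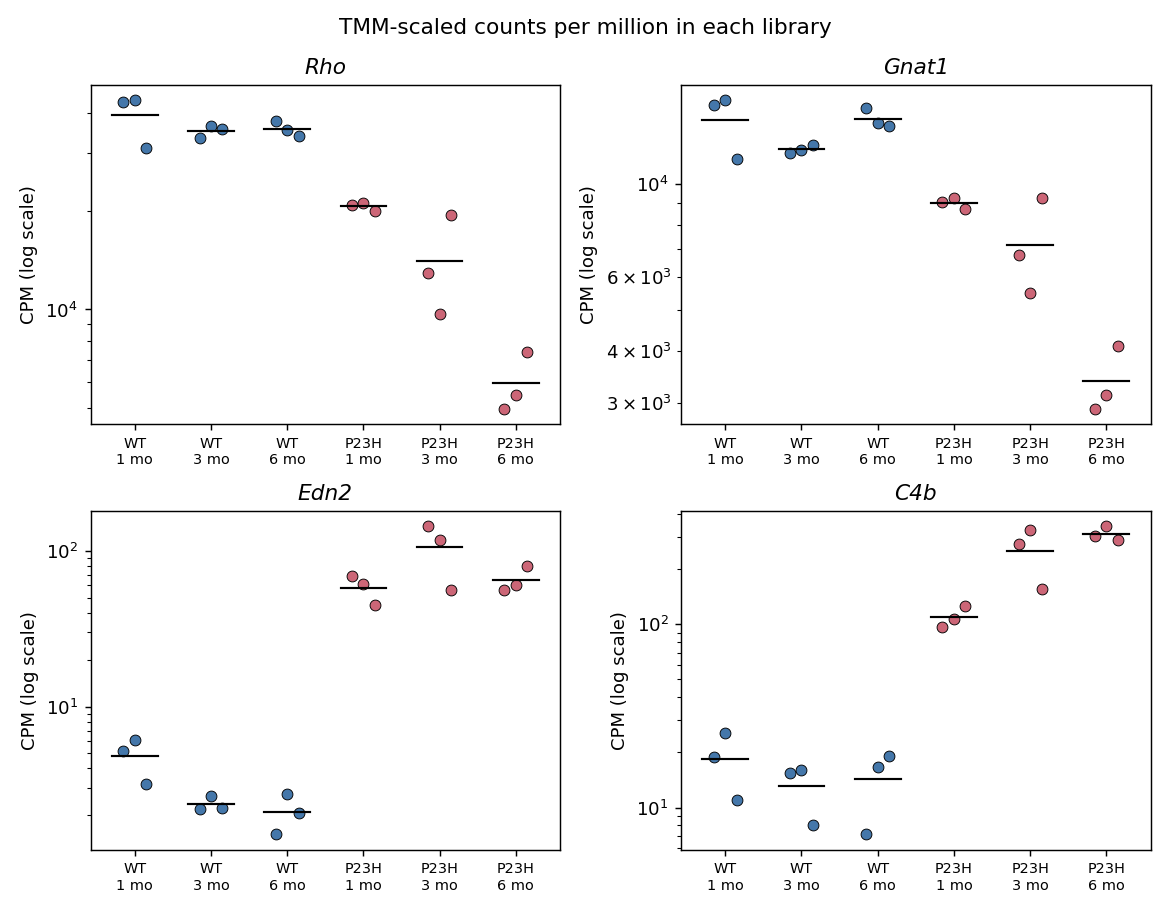
TMM-scaled CPM on log axes of Rho, the rod transducin gene Gnat1, Edn2 and C4b, by genotype and age, with a point per library and a line at each group mean. Rho lies between 31270 and 43580 CPM in wildtype libraries and between 4977 and 21160 CPM in P23H libraries.

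At 3 months rod genes were lower over most of their list and glial, complement and interferon genes were higher. Rho was at 35160 ± 1600 CPM (SD, n = 3) in wildtype and 14040 ± 5000 CPM in P23H, a change of -1.32 ± 0.21 (adjusted p = 0.000529). Under the naming rule, which asks that the libraries of the genotypes do not overlap, the largest rise was in Slc6a2, the noradrenaline transporter, from 0.233 to 16.8 CPM (6.12 ± 0.46, adjusted p = 2.59e-06), and Bcl3 (5.77 ± 0.63, 8 counts in all in wildtype) and Edn2 (5.48 ± 0.36, from 2.36 to 106 CPM) were also among the 6 largest. Alox15, a lipoxygenase, Slc34a2, a phosphate transporter, and Akr1b7, an aldose reductase, had fitted changes of 5.98 ± 1.39, 5.94 ± 1.54 and 5.68 ± 1.42 with 4, 7 and 10 counts in all in wildtype. Without P23H replicate 3 these 3 stood at 2.24, 2.77 and 2.82 and did not pass, Slc34a2 also did not without wildtype replicate 2, and Alox15 stood at 7.27 without wildtype replicate 3. The largest falls under the rule were in Glb1l3 (-4.36 ± 0.34, adjusted p = 3.02e-06, from 49.7 to 2.43 CPM), Slc17a4 (-2.36 ± 0.55, and -3.63 without P23H replicate 1), Col22a1 (-2.31 ± 0.28), Zan (-2.02 ± 0.36), Hdc (-1.91 ± 0.28) and Slc17a3 (-1.74 ± 0.25).

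In rod phototransduction 18 of 20 genes fell and none rose (18 adjusted over the list alone, median -0.89, camera adjusted p = 1.93e-19, and adjusted p = 0.0506 with an estimated correlation). Gucy2f, a photoreceptor guanylate cyclase, fell by 1.34 ± 0.16 (adjusted p = 5.58e-05), and Slc24a1 (-1.09 ± 0.17) and the anchor protein Rgs9bp (-1.06 ± 0.12) also fell. In outer segment and photoreceptor cilium 18 of 23 fell (21 adjusted over the list alone, median -0.69, camera adjusted p = 2.52e-14, and adjusted p = 0.0648 with an estimated correlation). They included the retinol dehydrogenase Rdh12 (-1.24 ± 0.12) and the axoneme protein Rp1 (-1.23 ± 0.16). Of 15 photoreceptor transcription factors 8 fell (11 lower and 1 higher adjusted over the list alone, median -0.42, camera adjusted p = 4.42e-06, and adjusted p = 0.047 with an estimated correlation). Nrl was at -1.13 ± 0.15, Mef2c at -0.997 ± 0.11 and Samd11 at -0.95 ± 0.12. That count was 5 without P23H replicate 2 or wildtype replicate 3. Of 17 photoreceptor synapse genes 11 fell (11 adjusted over the list alone, median -0.48, camera adjusted p = 1.28e-06, and adjusted p = 0.0443 with an estimated correlation). They included the active zone protein Rims2 (-0.94 ± 0.13) and the calcium channel Cacna1f (-0.90 ± 0.19). In the cone list 3 of 12 rose, Gnb3 (1.79 ± 0.16, adjusted p = 5.88e-06), Pde6c (0.53 ± 0.15) and Gngt2 (0.42 ± 0.15), with a median of 0.29 (camera adjusted p = 0.0108, and adjusted p = 0.622 with an estimated correlation). Only Gnb3 passed without P23H replicate 2, wildtype replicate 1 or wildtype replicate 3, and with inner neuron scaling.

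Of 18 reactive gliosis genes 14 rose (16 adjusted over the list alone, median 2.37, camera adjusted p = 1.48e-15, and adjusted p = 0.0192 with an estimated correlation). Gfap went from 15.9 to 153 CPM (3.26 ± 0.38, adjusted p = 4.53e-05), the metalloreductase Steap4 rose by 4.0 ± 0.64 (2.78 without P23H replicate 2), and the protease inhibitor Timp1 by 3.19 ± 0.56 (2.60 without P23H replicate 2). Of 16 Muller glia genes 11 rose and none fell (11 adjusted over the list alone, median 0.48, camera adjusted p = 1.8e-06, and adjusted p = 0.188 with an estimated correlation). They included the secreted chaperone Clu, from 686 to 1940 CPM (1.50 ± 0.21), and the lipid carrier Apoe (1.08 ± 0.19). The Muller count was 6 without P23H replicate 2, 7 without wildtype replicate 2 and 7 with inner neuron scaling. In stress and survival cytokine signalling 11 of 16 rose and 2 fell (the same counts adjusted over the list alone, median 1.32, camera adjusted p = 3.17e-17, and adjusted p = 0.00288 with an estimated correlation). Cebpd was at 3.35 ± 0.29 and Fgf2 at 3.23 ± 0.25. Of 16 immediate early genes 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.78, camera adjusted p = 0.000964, and adjusted p = 0.228 with an estimated correlation). Junb was at 1.23 ± 0.18 and Atf3 at 1.13 ± 0.15. That count of 9 was 5 without wildtype replicate 1 and 4 without wildtype replicate 3, and Klf4, at 3.01 ± 0.86, was at 0.78 without P23H replicate 3 and did not pass when any of the wildtype replicates was left out.

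In complement 12 of 16 genes rose (13 adjusted over the list alone, median 1.71, camera adjusted p = 1.49e-14, and adjusted p = 0.057 with an estimated correlation). C4b was at 252 CPM against 13.2 in wildtype (4.25 ± 0.39, adjusted p = 7.72e-06), Serping1 at 2.88 ± 0.41, and C3 at 3.20 ± 0.54 (2.28 without P23H replicate 2). In interferon response and antigen presentation 23 of 25 rose (23 adjusted over the list alone, median 1.88, camera adjusted p = 9.49e-29, and adjusted p = 0.0331 with an estimated correlation). They included the antiviral synthetase Oas1a (3.16 ± 0.53), Gbp2 (2.71 ± 0.25) and Bst2 (2.69 ± 0.29). In microglia and macrophage 20 of 23 rose (21 adjusted over the list alone, median 1.70, camera adjusted p = 1.03e-17, and adjusted p = 0.0648 with an estimated correlation). The lysosomal protein Cd68 was at 2.27 ± 0.34 and the integrin Itgam at 2.60 ± 0.36 (1.95 without P23H replicate 3). Beside these 3 lists, the erythrocyte list had a median of 1.02 with no member past the test, and Hbb-b1 was at 159 CPM in P23H replicate 3. Of 21 cell death genes 10 rose (12 adjusted over the list alone, median 0.75, camera adjusted p = 9.87e-07, and adjusted p = 0.0884 with an estimated correlation). They included the initiator caspase Casp8 (1.96 ± 0.27). Casp1, the inflammasome caspase, was at 4.51 ± 0.62 with 5 counts in all in wildtype, and Casp12 at 3.04 ± 0.67 was at 3.68 without wildtype replicate 1. Without P23H replicate 3, 5 cell death genes rose.

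In cornea, muscle and sclera 8 of 10 genes were higher at 3 months (10 adjusted over the list alone, median 3.79, camera adjusted p = 0.0146, and adjusted p = 0.644 with an estimated correlation). Without P23H replicate 3 none passed, and without wildtype replicate 1, 2 or 3 there were 2 each time. Krt5 at 6.30 ± 1.82, Krt14 at 5.85 ± 1.41 and Col3a1 at 3.98 ± 1.13 were at 1.2, 2.15 and 0.76 without that P23H library. Vascular genes had 3 of 17 higher (median 0.54, camera adjusted p = 0.000711, and adjusted p = 0.185 with an estimated correlation). They included Plvap, a protein of fenestrated endothelium (2.07 ± 0.20, adjusted p = 8.29e-06), and the pericyte gene Rgs5 (0.98 ± 0.15), and 5 passed without P23H replicate 1. In autophagy and lysosome 6 of 18 rose and 1 fell (median 0.27, camera adjusted p = 0.022, and adjusted p = 0.557 with an estimated correlation). The lysosomal protein Grn was at 0.75 ± 0.16. That count of 7 was 1 and 2 without P23H replicates 2 and 3, 2, 4 and 3 without wildtype replicates 1, 2 and 3, and 2 with inner neuron scaling. In cholesterol biosynthesis 4 of 19 rose (median 0.20, camera adjusted p = 0.0196, and adjusted p = 0.696 with an estimated correlation). The lipoprotein receptor Ldlr was at 1.12 ± 0.23 and the sterol sensor Insig1 at 0.59 ± 0.12. That count was 2 without P23H replicate 3, wildtype replicate 2 or wildtype replicate 3, 10 with library size alone and 2 with inner neuron scaling. In circadian clock 5 of 16 fell and 1 rose (median -0.23, camera adjusted p = 0.0177, and adjusted p = 0.49 with an estimated correlation). The repressor Cry1 was at -0.59 ± 0.09 and the repressor Bhlhe41 at -0.60 ± 0.10. That count of 6 was 3 without P23H replicate 2, wildtype replicate 1 or wildtype replicate 2.

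Endoplasmic reticulum genes went both ways at 3 months, with 9 of 25 lower and 1 higher and a median of -0.09, or 0.05 with library size alone (camera adjusted p = 0.0675). The chaperone Hspa5 was at -0.60 ± 0.14 (adjusted p = 0.00788), a call that ended with inner neuron scaling. Leaving out P23H replicates 1 and 2 and wildtype replicates 1, 2 and 3 gave 6, 4, 6, 3 and 3 of these genes past the test, library size alone gave 6 and inner neuron scaling 2. In the PERK-ATF4-CHOP response 4 of 17 rose, including Cebpb (1.17 ± 0.30), and 4 fell, including Trib3 (-0.81 ± 0.16), with a median of 0.30 (camera adjusted p = 0.625) and 5 past the test with inner neuron scaling. No retinal pigment epithelium gene passed (median 0.51), and none of the lens, whose median was 0.87 while camera ranked it downward (adjusted p = 0.807), with Ttr at 1.2 ± 0.61 and Cryaa at 1.08 ± 1.59. The other lists had few members past the test: bipolar cell 2 higher and 1 lower of 19, horizontal cell 0 of 7, amacrine cell 0 of 17, retinal ganglion cell 0 of 13, heat shock proteins 1 higher and 2 lower of 12, oxidative phosphorylation 1 of 44, and glycolysis and lactate 5 lower of 21. Left-out libraries moved these to 0 bipolar genes (P23H replicate 2 or any wildtype replicate), 5 heat shock genes (P23H replicate 3), 3 and 2 glycolysis genes (P23H replicate 2 and wildtype replicate 2), and 6 oxidative phosphorylation genes (P23H replicate 1).

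At 3 months 3924 genes passed (2043 higher, 1881 lower). It was 2468 without P23H replicate 2, 2533 without wildtype replicate 3, 2174 with inner neuron scaling and 1760 with only the libraries compared. The split was 2465 higher and 1425 lower with upper-quartile scaling and 3570 and 893 with library size alone. It was 1160 and 3476 in limma but 1825 and 1879 with its factor used once.

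At 6 months every gene of rod phototransduction was lower in P23H, and genes of gliosis, complement and microglia were higher over nearly all of their lists. Rho was at 35700 ± 1890 CPM (SD, n = 3) in wildtype and 5956 ± 1290 CPM in P23H, a 5.99-fold fall (-2.58 ± 0.22, adjusted p = 3.96e-07). Among the largest rises under the naming rule were Slc6a2 (5.34 ± 0.42, from 0.482 to 19.8 CPM), Edn2 (4.95 ± 0.36, from 2.11 to 65.5 CPM), Steap4 (4.49 ± 0.65) and C4b (4.44 ± 0.40, from 14.3 to 312 CPM). The urokinase Plau rose by 4.19 ± 0.68 (5.47 without wildtype replicate 3), and the class II antigen chain H2-Aa, of a family with shared reads, by 4.17 ± 0.56 (4.77 without wildtype replicate 2). The largest falls under it were in Glb1l3 (-5.14 ± 0.35, adjusted p = 6.59e-08, from 78.6 to 2.22 CPM), Lrch4 (-3.94 ± 1.18), Slc17a4 (-3.56 ± 0.58), the LIM protein Csrp3 (-3.56 ± 0.38), Hdc (-3.31 ± 0.30) and Zan (-2.80 ± 0.37). Lrch4 stood at -10.45 without P23H replicate 1, and its call ended without P23H replicate 2.

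In rod phototransduction 20 of 20 genes fell, also adjusted over the list alone (median -1.94, camera adjusted p = 2.36e-38, and adjusted p = 0.0111 with an estimated correlation). Gucy2f fell by 2.63 ± 0.17, Slc24a1 by 2.35 ± 0.18 and the phosphodiesterase Pde6a by 2.19 ± 0.17. In outer segment and photoreceptor cilium 23 of 23 fell, also adjusted over the list alone (median -1.58, camera adjusted p = 3.24e-32, and adjusted p = 0.0111 with an estimated correlation). Rp1 was at -2.30 ± 0.16, Prph2 at -2.03 ± 0.15 and the retinoid flippase Abca4 at -1.99 ± 0.18. Of 15 photoreceptor transcription factors 13 fell (13 lower and 1 higher adjusted over the list alone, median -1.11, camera adjusted p = 2.02e-13, and adjusted p = 0.00858 with an estimated correlation). Nrl was at -2.14 ± 0.15, Esrrb at -2.08 ± 0.15 and Nr2e3 at -1.81 ± 0.17. Of 17 photoreceptor synapse genes 14 fell and 1 rose (median -1.06, camera adjusted p = 4.57e-11, and adjusted p = 0.013 with an estimated correlation). The calcium sensor Cabp4 was at -1.62 ± 0.10 and Rims2 at -1.41 ± 0.13. In the cone list Gnb3 rose by 1.23 ± 0.15, while Opn1sw, the short-wavelength opsin (-0.89 ± 0.29, adjusted p = 0.0206), and Kcne2 fell. That list's median was 0.06, or -0.11 with inner neuron scaling (camera adjusted p = 0.76), and the Opn1sw call ended with library size alone and without wildtype replicate 1 or 3. The Kcne2 call ended with library size alone and without P23H replicate 3. Glycolysis and lactate, described here because as many of its members passed as did not, had 8 of 21 lower and 3 higher (median -0.23, or 0.06 with library size alone, camera adjusted p = 0.0968), with the hexokinase Hk2 at -1.55 ± 0.17 and the lactate transporter Slc16a1 at -1.06 ± 0.12.

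Glial and immune lists were higher over most members. In reactive gliosis 17 of 18 rose (median 2.71, camera adjusted p = 1.3e-10, and adjusted p = 0.0506 with an estimated correlation). Serpina3n, a secreted serpin, was at 3.97 ± 0.68. In Muller glia 14 of 16 rose (median 0.78, camera adjusted p = 1.11e-07, and adjusted p = 0.126 with an estimated correlation). Clu was at 1.88 ± 0.21 and the peroxiredoxin Prdx6 at 1.32 ± 0.14. In microglia and macrophage 23 of 23 rose (median 2.20, camera adjusted p = 1.25e-13, and adjusted p = 0.119 with an estimated correlation). Aif1 was at 2.74 ± 0.42, and with Lyz2 and Gpnmb at 3.83 ± 0.72 and 2.92 ± 0.69, which were 4.81 and 3.99 without wildtype replicate 3. In complement 15 of 16 rose (16 adjusted over the list alone, median 2.30, camera adjusted p = 6.9e-12, and adjusted p = 0.0884 with an estimated correlation), with C3 at 4.10 ± 0.57 and Serping1 at 3.57 ± 0.42. In interferon response and antigen presentation 23 of 25 rose (median 2.40, camera adjusted p = 3.9e-19, and adjusted p = 0.0648 with an estimated correlation). The invariant chain Cd74 was at 3.86 ± 0.57 and Oas1a, with 7 counts in all in wildtype, at 4.64 ± 0.57, or 5.23 without wildtype replicate 2. In stress and survival cytokine signalling 12 of 16 rose and 1 fell (median 1.72, camera adjusted p = 2.1e-09, and adjusted p = 0.0111 with an estimated correlation). Cebpd was at 3.21 ± 0.29 and the cytokine Lif at 2.32 ± 0.42, or 3.03 without wildtype replicate 3. In cell death 14 of 21 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.77, camera adjusted p = 0.000476, and adjusted p = 0.215 with an estimated correlation). The death receptor Fas was at 2.55 ± 0.56 and the receptor Tnfrsf1a at 2.25 ± 0.27. Immediate early genes had 6 of 16 higher and 1 lower (median 0.48, camera adjusted p = 0.0454, and adjusted p = 0.507 with an estimated correlation). Egr3 was at 2.27 ± 0.41 and Junb at 1.01 ± 0.18.

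Lists of neighbouring tissues differed in how many of their genes passed. In retinal pigment epithelium 8 of 12 genes rose (median 1.33, camera adjusted p = 0.00138, and adjusted p = 0.395 with an estimated correlation). Slc45a2, Pmel, Mlana and Tyrp1, all melanosome genes, rose by 3.69 ± 0.60, 3.52 ± 0.77, 3.51 ± 0.75 and 3.23 ± 0.71, and by 4.84, 4.88, 4.49 and 4.38 without wildtype replicate 3. Erythrocyte genes had 5 of 7 higher (median 2.23, camera adjusted p = 0.0395, and adjusted p = 0.605 with an estimated correlation). Hbb-b1 was at 2.23 ± 0.63 and Hba-a1 at 2.22 ± 0.65. Vascular genes had 12 of 17 higher (median 0.88, camera adjusted p = 0.000964, and adjusted p = 0.188 with an estimated correlation). Plvap was at 1.49 ± 0.19 and the endothelial receptor Kdr at 1.32 ± 0.24, and 7 without P23H replicate 2. In the lens list only Cryab passed, a small heat shock protein that the heat shock list also holds (3.63 ± 1.34, adjusted p = 0.0369), while the median was 2.18 (camera adjusted p = 0.0978). Its call ended without P23H replicate 3 (1.52) and without wildtype replicate 1, 2 or 3, and with a block for replicate number (2.74). In cornea, muscle and sclera 2 of 10 were higher, and 1 without P23H replicate 2 or 3 or wildtype replicate 1 or 2.

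Bipolar cell genes had 12 of 19 higher and 2 lower (14 and 2 adjusted over the list alone, median 0.49, camera adjusted p = 0.022, and adjusted p = 0.687 with an estimated correlation). Isl1 was at 0.87 ± 0.16 and Gng13 at 0.86 ± 0.18 higher, Lrit3, a synaptic protein of ON bipolar cells, at -1.56 ± 0.22, 9 past without P23H replicate 1 and 8 with inner neuron scaling. In the PERK-ATF4-CHOP response 7 of 17 rose and 5 fell (median 0.03, or -0.13 with inner neuron scaling, camera adjusted p = 0.864), with Cebpb at 2.26 ± 0.30 and the cystine transporter Slc7a11 at 1.47 ± 0.34. Endoplasmic reticulum genes had 9 of 25 lower and 4 higher (median -0.13, or 0.15 with library size alone, camera adjusted p = 0.294), with the stress sensors Ern1 at -0.88 ± 0.18 and Atf6 at -0.71 ± 0.11 and the ERAD protein Herpud1 at 0.57 ± 0.09. Heat shock proteins had 3 of 12 higher and 3 lower, with the co-chaperone Bag3 at 1.37 ± 0.24 and the inducible chaperone Hspa1a at -1.12 ± 0.19. That list's median was 0.02, or -0.14 with inner neuron scaling, its mean 0.34, and camera ranked it downward (adjusted p = 0.933). Autophagy and lysosome had 9 of 18 higher (median 0.29, camera adjusted p = 0.0102, and adjusted p = 0.49 with an estimated correlation). The cathepsin Ctsl was at 1.42 ± 0.34, and 15 with library size alone. Among the other lists, oxidative phosphorylation had 15 of 44 higher and 2 lower, circadian clock 4 higher and 3 lower of 16, amacrine cell 3 higher and 1 lower of 17, cholesterol biosynthesis 2 higher and 2 lower of 19, horizontal cell 1 of 7 and retinal ganglion cell 1 of 13. Oxidative phosphorylation went from 17 in all to 9, 9 and 10 without P23H replicate 3 and wildtype replicates 1 and 3, and to 37 with library size alone and 1 with inner neuron scaling. Cholesterol biosynthesis went from 4 to 7, 2 and 1 without P23H replicates 1, 2 and 3 and 2 without wildtype replicate 2, and the horizontal cell gene did not pass without P23H replicate 2 or wildtype replicate 1 or 3. At 6 months the ganglion and horizontal cell medians were -0.11 and -0.06 while camera ranked both upward, and at 3 months the horizontal cell median was 0.03 while camera ranked it downward. The heat shock median and mean at 3 months were -0.04 and 0.05, and those of Muller glia at 1 month -0.01 and 0.06.

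At 6 months 7070 genes passed (3555 higher, 3515 lower), and 4076 also changed by over 1.5-fold. No left-out library moved that count by over 1.5 times. The split was 4374 higher and 2768 lower with upper-quartile scaling and 6670 and 1534 with library size alone. It was 1952 and 3846 with inner neuron scaling, 1994 and 6200 in limma, and 3628 and 3445 with limma's factor used once. The median change of all genes was 0.007, 0.01 and 0.03 at 1, 3 and 6 months with TMM. It was 0.16 at 3 months and 0.31 at 6 months with library size alone, 0.12 at 6 months with upper-quartile scaling, and 0.19 at 1 month and -0.13 at 6 months with inner neuron scaling.

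**Figure D3:**
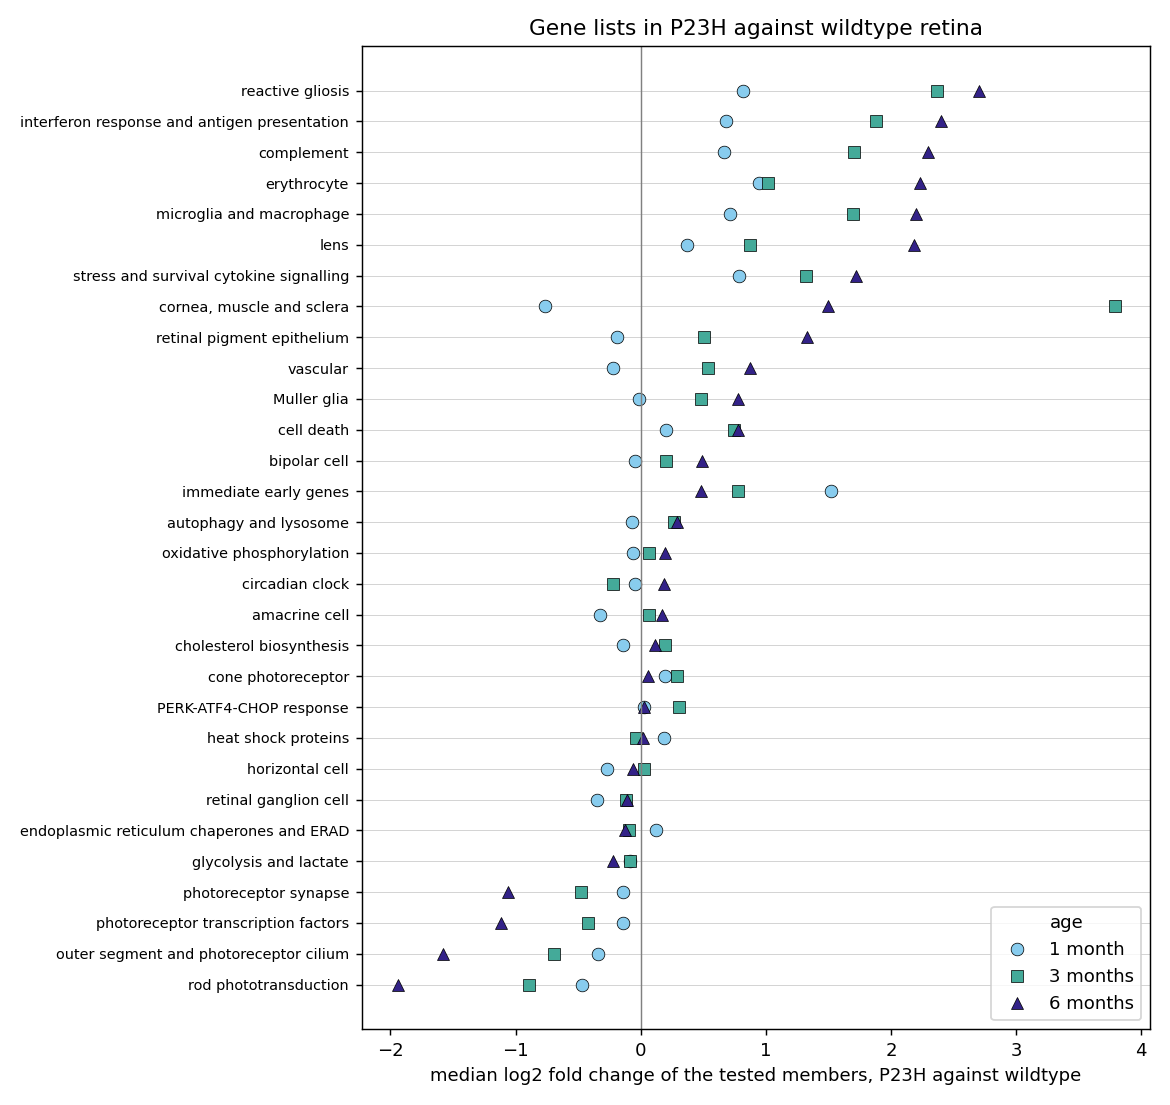
Median log2 change of the tested members of 30 gene lists in P23H against wildtype, with circles for 1 month, squares for 3 months and triangles for 6 months. Rod phototransduction lies at -0.47, -0.89 and -1.94, reactive gliosis at 0.82, 2.37 and 2.71, and medians close to 0 change sign with the scaling.

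Averaged over all ages, the genotype effect passed the test for Rho and for these other genes named at single ages. Rho fell by 1.61 ± 0.12 (adjusted p = 8.72e-08), Glb1l3 by 4.15, Hdc by 2.28 and Nrl by 1.35, while Edn2 rose by 4.67, C4b by 3.75 and Gnb3 by 1.43. In that average effect 7047 genes passed (3624 higher, 3423 lower). The split was 6873 and 1464 with library size alone and 4408 and 2707 with upper-quartile scaling. It was 2009 and 6550 in limma, and 3568 and 3396 with its factor used once. At all 3 ages 146 genes were higher and 105 lower. Between 1 and 3 months 172 genes were higher at both ages where 54.6 would be shared if calls were independent, and 107 were lower where 43.7 would be. Between 3 and 6 months the shared numbers were 1553 (457 if independent) and 1725 (416 if independent).

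In wildtype retina between 1 and 6 months, Csrp3 rose from 0.794 to 6.38 CPM (2.99 ± 0.37, adjusted p = 0.00101), Glb1l3 from 14.8 to 78.6 CPM (2.41 ± 0.29, adjusted p = 0.00101), Rimbp3 by 2.13 ± 0.31 and Hdc by 1.78 ± 0.28. The lens crystallins Cryge (-8.38 ± 1.33) and Crygn (-6.72 ± 1.44) and the collagen Col6a3 (-5.17 ± 1.23) were among the largest falls under the naming rule. Cryge stood at -7.72 without 1-month replicate 3 and -10.04 without 6-month replicate 2. Crygn and Col6a3 did not pass when 1-month replicate 2 or any of the 6-month replicates was left out or with inner neuron scaling, and Crygn stood at -5.75 without 1-month replicate 3. Crygf, the other crystallin among them, had 3 counts in all at 6 months and 1581 at 1 month, so its fitted change rests on few counts. It did not pass without 1-month replicate 1 or 2, without any of the 6-month replicates, or with inner neuron scaling (adjusted p from 1.37e-05 to 0.152 over the alternatives). The lens list had a median of -4.34 with 0 of 17 past the test and 11 lower adjusted over the list alone (camera adjusted p = 3.79e-07, and adjusted p = 0.564 with an estimated correlation). Between 1 and 3 months Glb1l3 (1.75 ± 0.29), the kinase Alpk2 (1.43 ± 0.20), Fam159b (1.30 ± 0.21) and the chaperone Sdf2l1 (1.03 ± 0.16) rose, with adjusted p between 0.0171 and 0.0425. None of the 4 passed without 1-month replicate 1 or 2 or 3-month replicate 2 or 3, and Glb1l3 also did not without 3-month replicate 1.

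From 1 to 6 months 353 wildtype genes passed (189 higher, 164 lower). It was 160, 38 and 2490 without 1-month replicates 1, 2 and 3, and 138, 146 and 63 without 6-month replicates 1, 2 and 3. Scaling on inner neurons gave 57, a term for the lens score 52, DESeq2 1170 and only the libraries compared 8. From 1 to 3 months 7 wildtype genes passed, all higher. It was 0, 0 and 1732 without 1-month replicates 1, 2 and 3, 0 and 1 without 3-month replicates 2 and 3, 3 with a block for replicate number, 1 with inner neuron scaling and 267 with DESeq2. From 3 to 6 months edgeR gave 0 genes, with 641 at an unadjusted p under 0.05, DESeq2 gave 7, limma on the deposited CPM gave 0, and edgeR on only the libraries compared gave 53. The lens list had a median of -3.95 in that comparison, with 0 of 17 past and 16 lower adjusted over the list alone (camera adjusted p = 1.41e-25, and adjusted p = 0.17 with an estimated correlation).

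In P23H retina, rod genes fell further with age. Between 1 and 6 months Rho fell by 1.80 ± 0.22 (adjusted p = 3.26e-05), Gucy2f by 2.01, Rp1 by 2.02, Nrl by 1.41 and Fosb by 1.71 (adjusted p = 1.41e-05). In rod phototransduction 20 of 20 genes fell (median -1.37, camera adjusted p = 1.48e-33, and adjusted p = 0.028 with an estimated correlation). The largest rises under the naming rule included the matrix protein Dcn (5.05 ± 1.00) and the connexin Gjb2 (4.29 ± 0.95), and the paralogs Prb1 and Prpmp5, which had 3 and 0 counts in all at 1 month and 746 and 422 at 6 months. The largest falls under it were in the crystallins Cryge (-7.66), Crygf (-5.64) and Cryga (-5.39, with 9 counts in all at 6 months), and in Lrch4 (-3.92). Cryge stood at -9.43 and Lrch4 at -10.43 without 6-month replicate 1. Crygf did not pass when any of the 6-month replicates was left out, nor Cryga when any replicate of either age was. Lrch4 did not pass without 1-month replicate 3 or 6-month replicate 2 or 3. Gjb2 stood at 4.95 without 1-month replicate 2. Between 1 and 3 months Egr4 (-3.04 ± 0.47), Nr4a3 (-2.98 ± 0.50), the deiodinase Dio2 (-2.31 ± 0.37) and Nr4a1 (-1.79 ± 0.18, adjusted p = 0.000471) fell, and Nr4a3 stood at -3.68 without 3-month replicate 3. The largest rises there under the rule were in Defb1 (4.98 ± 1.18, with 9 counts in all at 1 month), Asprv1 (4.42 ± 1.07), and Alox15 and Rab25, which had 1 and 3 counts in all at 1 month. Defb1, Asprv1 and Rab25 did not pass when 3-month replicate 3 or any of the 1-month replicates was left out, and Alox15 did not without 1-month replicate 1 or 2. Between 3 and 6 months Rho fell by 1.24 ± 0.21 (adjusted p = 0.00429), Fgf2 by 1.26 ± 0.22 and the tight junction gene Cldn23 by 1.30 ± 0.34, Cryge fell by 5.79 ± 1.44, and the smooth muscle genes Myh11 (4.45 ± 0.87) and Tagln (3.55 ± 0.45) rose. Cryge stood at -2.57 and Cldn23 at -0.84 without 3-month replicate 3, and neither passed when it or any of the 6-month replicates was left out. The rod list fell in 20 of 20 genes there too (median -0.90, camera adjusted p = 8.07e-48, and adjusted p = 0.0115 with an estimated correlation).

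With age in P23H, 3 against 1 month, 2024 genes passed (974 higher, 1050 lower). It was 453, 724 and 1042 without 1-month replicates 1, 2 and 3, and 3141, 987 and 976 without 3-month replicates 1, 2 and 3. Inner neuron scaling gave 664, a term for the cornea score 830 and only the libraries compared 1. From 1 to 6 months 4529 P23H genes passed (2069 higher, 2460 lower), and 3016 without 6-month replicate 2. Its split was 5085 and 1142 with library size alone and 590 and 3239 with inner neuron scaling. At the preset correlation, camera called 12, 10 and 12 of the 31 lists in wildtype and 13, 16 and 14 in P23H for 3 against 1, 6 against 1 and 6 against 3 months. With an estimated correlation these were 0, 0 and 0 in wildtype and 0, 4 and 3 in P23H. From 3 to 6 months 490 P23H genes passed (117 higher, 373 lower). It was 781 without 3-month replicate 2, 173 without 6-month replicate 2, 858 with DESeq2 and 0 when only the libraries compared were fitted. Its split was 364 and 174 with library size alone and 34 and 301 with inner neuron scaling.

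The genotype effect itself was tested for a difference between ages. Rho's effect was larger at 6 months than at 1 month by -1.66 (adjusted p = 0.00117) and than at 3 months by -1.26 (adjusted p = 0.0489), and the difference between 3 months and 1 month was -0.40 (adjusted p = 0.368). Of the 12 libraries of 3 and 6 months, only P23H 3-month replicate 2 and P23H 6-month replicate 3 could be left out with the call on Rho from 3 to 6 months kept (adjusted p from 0.000775 to 0.146 over the alternatives). Rod phototransduction had 20 of 20 genes lower in the difference of 6 months from 1 month (median -1.46, camera adjusted p = 8.48e-24, and adjusted p = 0.0373 with an estimated correlation) and 17 of 20 from 3 months (median -1.04, camera adjusted p = 1.4e-39, and adjusted p = 0.0111 with an estimated correlation). Gucy2f, with differences of -2.41 from 1 month and -1.29 from 3 months, and the regulators Nr2e3 (-1.39 ± 0.24) and Mef2c (-1.11) from 3 months followed the list. In interferon response 21 of 25 had a larger effect at 6 months than at 1 month and 1 a smaller (median 1.47, camera adjusted p = 1.81e-08, and adjusted p = 0.263 with an estimated correlation). Cd74 was at 3.39 and Steap4, of the gliosis list, at 4.15 ± 0.89. Immediate early genes had 5 of 16 with a smaller effect at 6 months and 1 with a larger (median -0.66, camera adjusted p = 0.0306, and adjusted p = 0.481 with an estimated correlation). Fosb was at -2.69 (adjusted p = 2.74e-05). Between 1 and 3 months the effect on the endoplasmic reticulum factors Xbp1 (-1.06, adjusted p = 0.00532) and Hspa5 (-1.04, adjusted p = 0.00898) and on Dio2 (-3.21 ± 0.51, adjusted p = 0.00357) became lower, and on Plvap (1.73, adjusted p = 0.00357) higher.

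For the difference of effects, camera called 17, 18 and 15 of the 31 lists for 3 against 1, 6 against 1 and 6 against 3 months at the preset correlation, and 0, 4 and 4 of them with an estimated correlation. Between 6 months and 1 month the effect differed for 4704 genes (2086 with a higher and 2618 with a lower effect), and no left-out library moved it by over 1.5 times. Its split was 3851 and 1377 with library size alone and 388 and 3604 with inner neuron scaling. Between 3 months and 1 month it differed for 2152 genes (846 and 1306). It was 808 and 1167 without 1-month P23H replicates 1 and 2, 3386, 1271 and 1325 without 3-month P23H replicates 1, 2 and 3, 616, 580 and 4136 without 1-month wildtype replicates 1, 2 and 3, and 1215, 857 and 1030 without 3-month wildtype replicates 1, 2 and 3. With inner neuron scaling it was 861 (56 and 805), and with a term for the cornea score 787. Between 6 and 3 months it differed for 215 genes (31 and 184). It was 79, 464 and 137 without 3-month P23H replicates 1, 2 and 3, 133 and 59 without 6-month P23H replicates 1 and 2, 104, 77 and 50 without 3-month wildtype replicates 1, 2 and 3, and 61 and 95 without 6-month wildtype replicates 1 and 3. It was 46 with inner neuron scaling, 105 with library size alone, 521 with DESeq2 and 15 with only the libraries compared.

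**Figure D4:**
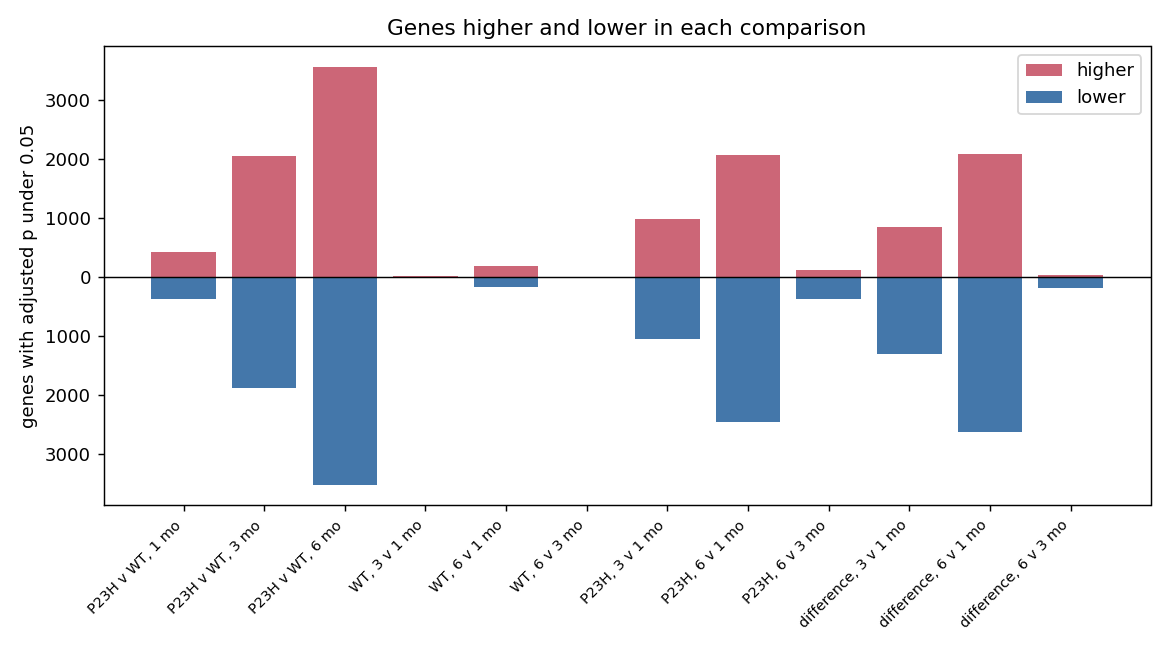
Genes with an adjusted p under 0.05 in each comparison, with bars upward for higher and downward for lower. Genotype bars reach 425 and 369 genes at 1 month, 2043 and 1881 at 3 months and 3555 and 3515 at 6 months, and wildtype at 6 against 3 months has 0.

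The stated rule of the authors (p under 0.05 and over 1.5-fold) gives 1000, 2530 and 4268 genes at 1, 3 and 6 months in the authors' deposited full tables, and the authors' deposited tables of called genes hold fewer. They list 655 genes higher and 242 lower at 1 month, 1441 and 786 at 3 months and 2385 and 1627 at 6 months. Of the listed genes, 342, 1817 and 3737 also passed the test here. In the authors' deposited table the fold change of Rho is -1.89, -2.5 and -5.96 at the same ages. The adjusted p in the authors' deposited tables is under 0.05 for 477, 2996 and 5883 genes at 1, 3 and 6 months. For age it is under 0.05 for 46, 506 and 7 genes in wildtype and 1367, 3474 and 324 in P23H, for 3 against 1, 6 against 1 and 6 against 3 months.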

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

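Chosen only after the result was seen were the tests of cornea genes, immediate early genes, cell composition and blood at 6 months. So were the sex, lens and cornea terms.

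The genotype effect was tested for a difference between ages with contrasts of the same model, and those that differed are given here. Effects differed for 2152 genes between 3 months and 1 month, 4704 between 6 months and 1 month and 215 between 6 and 3 months. Among 100 drawn regroupings the highest other counts were 852, 4511 and 7756, of which 852 and 4511 lay below the real counts. For 6 with 3 months 6 of 100 gave as many, the real one included, and the other 5 all held the genotypes apart at 6 months. The highest, with 7756 genes, exchanged the genotypes at that age and so added the effects of both ages, which points to that structure of the samples. Regrouping genotypes within ages does not stand for an unchanged effect, so the draws decide nothing on chance for any of these differences. Draws that mix genotypes within a group also widen its spread, which can lower their counts.

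Between 3 months and 1 month, log2 differences were 10.63 for Tnni2, 9.56 for Tnnt3, 8.72 for Myl1 and 8.58 for Alox15. Tnni2, Tnnt3 and Alox15 had 1, 3 and 1 counts in all in P23H at 1 month, so these fitted values rest on few counts. Without P23H 3-month replicate 3 the 4 differences were 4.90, 3.76, 3.72 and 4.84 and did not pass. They also did not pass when any P23H replicate of 1 month, any wildtype replicate of 3 months, or wildtype 1-month replicate 1 or 2 was left out, or with inner neuron scaling, and Tnni2, Tnnt3 and Myl1 stood at 3.86, 6.32 and 5.20 without wildtype 1-month replicate 1. Lower effects at 3 months were found for Dio2 (-3.21), Nr4a3 (-2.71), Slc17a4 (-2.41) and Egr4 (-2.24). The calls of Slc17a4 and Egr4 ended when any library of the comparison but P23H 3-month replicate 1 or wildtype 1-month replicate 3 was left out. That of Nr4a3 ended without P23H 1-month replicate 2, P23H 3-month replicate 2, wildtype 1-month replicate 1 or wildtype 3-month replicate 1 or 2. Slc17a4 stood at -3.68 without P23H 3-month replicate 1, and Nr4a3 at -3.41 without P23H 3-month replicate 3. Between 6 months and 1 month, differences were 4.83 for Plau (6.12 without wildtype 6-month replicate 3, 4.14 without wildtype 1-month replicate 2), 4.74 for Dcn (6.24 without that 6-month library), 4.16 for Slc45a2 (5.32 without that 6-month library), 4.15 for Steap4, -3.61 for Slc17a4, -3.33 for Dio2, -2.98 for Csrp3 and -2.94 for Rimbp3. Between 6 and 3 months, they were 3.45 for Tagln (4.41 without wildtype 6-month replicate 3), 2.48 for Myl9, 2.06 for Adamts16, 1.95 for Smtn, -1.54 for Fgf2, -1.42 for Diap3, -1.39 for Nr2e3 and -1.37 for Fhod3. The calls of Myl9, Adamts16, Smtn and Fgf2 ended when any library of the comparison was left out, except P23H 3-month replicate 2 for all of them, P23H 6-month replicate 3 for Myl9, Adamts16 and Smtn, and wildtype 6-month replicate 3 for Myl9 and Smtn. Tagln, Myl9, Adamts16 and Smtn also did not pass with inner neuron scaling (Tagln at 3.25, adjusted p = 0.0533, with a range of 2.84e-06 to 0.0533 over its alternatives), nor Adamts16, Smtn and Fgf2 with library size alone. List medians of the difference between 6 months and 1 month were -1.46 for rod phototransduction, -1.24 for outer segment and photoreceptor cilium, -1.19 for photoreceptor transcription factors and -0.88 for photoreceptor synapse. Between 6 and 3 months the same lists had medians of -1.04, -0.85, -0.60 and -0.42.

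Genes of cornea, muscle and sclera were higher in P23H at 3 months in 8 of 10 members, with Krt12 at 924 CPM in P23H replicate 3. Tissue from outside the retina in that library may account for the calls, since 0 of 10 members passed without it. Whether genotype also raises these genes at 3 months cannot be told apart from this, because 2 of 10 members lay above all 3 wildtype libraries in both other P23H libraries, between the bounds set for the test.

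Of 16 immediate early genes 9 were higher in P23H at 1 month. Sex was balanced (female pattern in P23H replicate 3 and wildtype replicate 2), which argues against it, and 9 passed with its term. Handling or time of dissection that differed between groups, not in the labels, could account for them and cannot be told apart from genotype. With them 0 of 12 heat shock proteins rose. Genotype stays open too: 5 of the 9 were higher at 3 months, 4 at 6 and 3 at both (Fosl2, Junb, Egr2).

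Microglia, complement and interferon genes were higher in P23H at 3 and 6 months. A smaller share of rod RNA that raises all other cell types alike is argued against, since at 6 months the median of the 3 lists (2.3 over 64 members, lower quartile 1.7) exceeded that of 56 inner neuron genes (0.17, upper quartile 0.49) by 2.13. Sex is argued against as well, since all 61 members past at 6 months passed with a term for it. Blood left in the eye is argued against at 3 months, where without P23H replicate 3 the erythrocyte median was -0.12 and that of the lists 1.79. At 6 months blood cannot be told apart from a tissue change, with 7 erythrocyte genes at a median of 2.23. A response of the mutant retina stays open, and immune and activated resident cells were not separated.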

How the results depend on the processing

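Chosen only after seeing the data were the sex, lens and cornea terms, limma with the factor used once, and the GC and length trends.

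Depth of 16.3 to 21.8 M counts per library leaves genes with few counts in a group without a firm fold. Over the alternatives, named genes kept their direction and side of the threshold in 9432 cases, were weaker in 1472, stronger in 24 and reversed in 1, and DESeq2 gave no adjusted p for Tnnt3 and Myl1. The reversed value is Krt12 at 3 months, at -1.66 without P23H 3-month replicate 3, the library that held the high Krt12 level, and at up to 6.38 without another. Set tests kept their side of the threshold in 659 cases, were weaker in 65 and stronger in 20. Gene counts stayed within 1.5 times in 239 cases and moved in 102. The cause was not tested, except limma's repeated factor and where fewer libraries or a stricter or looser rule make the change.

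For P23H against wildtype at 1 month, 794 genes became 255 with inner neuron scaling, 1597 with DESeq2, 1443 in limma on the deposited CPM, 231 with only the libraries compared and 369 with 1.5-fold added. At 3 months, 3924 became 2174 with inner neuron scaling, 1760 with only the libraries compared and 2108 with 1.5-fold added. At 6 months, 7070 became 4418 by unadjusted p and 1.5-fold and 4076 with 1.5-fold added, and over all ages 7047 became 2481 and 2266.

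In wildtype from 1 to 3 months, 7 genes became 3 with a replicate block and 3 with a sex term, 1 with inner neuron scaling, 267 with DESeq2, 13 in limma on the deposited CPM and 13 with its factor used once, 20 with the GC trend and 20 with the length trend taken out, 0 with only the libraries compared and 651 by unadjusted p and 1.5-fold. From 1 to 6 months, 353 became 57 with inner neuron scaling, 1170 with DESeq2, 52 with a lens term, 8 with only the libraries compared, 1248 by unadjusted p and 1.5-fold and 221 with 1.5-fold added. From 3 to 6 months, 0 in edgeR (641 by unadjusted p) became 7 with DESeq2, 53 with only the libraries compared and 271 by unadjusted p and 1.5-fold.

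In P23H from 1 to 3 months, 2024 genes became 664 with inner neuron scaling, 830 with a cornea term, 918 with 1.5-fold added and 1 with only the libraries compared. From 1 to 6 months, 4529 became 2838 by unadjusted p and 1.5-fold and 2318 with 1.5-fold added. From 3 to 6 months, 490 became 858 with DESeq2, 1188 in limma on the deposited CPM, 0 with only the libraries compared, 815 by unadjusted p and 1.5-fold and 261 with 1.5-fold added.

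Differences of the genotype effect between 3 months and 1 month went from 2152 genes to 861 with inner neuron scaling, 1434 with a sex term, 787 with a cornea term and 948 with only the libraries compared. Those between 6 and 3 months went from 215 to 105 with library size alone, 46 with inner neuron scaling, 521 with DESeq2, 500 in limma on the deposited CPM, 75 with a lens term, 15 with only the libraries compared and 875 by unadjusted p and 1.5-fold.

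Leaving out a library at a time, genotype counts ranged from 185 to 3163 at 1 month, 2468 to 4927 at 3 months, 5692 to 6957 at 6 months and 6340 to 7601 over all ages. Wildtype age counts ranged from 0 to 1732, 38 to 2490 and 0 to 0 for 3 against 1, 6 against 1 and 6 against 3 months, and P23H age counts from 453 to 3141, 3016 to 4304 and 173 to 781. Differences of effects ranged from 580 to 4136, 3177 to 5944 and 50 to 464 for the same pairs of ages.

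With replicate number as a block, genotype counts were 701, 3794 and 7012 at 1, 3 and 6 months. The numbers were not taken to pair the libraries, since not every same-number pair correlated over 0.1 in its residuals. Of 45 such pairs 14 did (from -0.305 to 0.603, mean 0.0397), while the 90 other pairs lay between -0.476 and 0.292. Of 18 libraries 9 correlated best with a library of their own number, where 6 would by chance, so a structure shared by some same-number libraries is not excluded.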

Other observations

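Chosen only after the result was seen were the tests of rod gene heterogeneity and of the other split of the 1-month libraries. So were those with GC, length and lens terms, including on the genes that rose with age.

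The genes that rose with age in wildtype may be held at a lower level in P23H. This hypothesis was read at 3 months, which the comparison of 6 with 1 month does not use. Of the 189 genes that rose between 1 and 6 months in wildtype, 107 (56.6%) were lower in P23H at 3 months, against 11.3% of the other genes, a ratio of 5.01 (Fisher's exact p = 2.47e-50), and 13 were higher. Of the 164 genes that fell with age in wildtype, 81 (49.4%) were higher in P23H at 3 months, against 12.5% of the others. The 353 calls behind both sets became 57 with inner neuron scaling and 38 to 2490 without a library, where the overlap was not tested. In the rising set Csrp3, Glb1l3 and Hdc were at 3.04, 49.7 and 35.4 CPM in wildtype at 3 months and 1.02, 2.43 and 9.44 in P23H. Across genes, which are not independent replicates, each library's deviation from the gene means was correlated with transcript GC content. Values were -0.115, -0.0851 and -0.203 in wildtype at 6 months and 0.136, 0.15 and -0.217 at 1 month. At 3 months they were 0.053, -0.251 and -0.144 in wildtype and 0.0972, 0.137 and 0.192 in P23H. A GC difference could therefore run the same way in both. It is argued against as the whole cause. With GC trends taken out 116 of 204 rising genes (56.9%) were lower at 3 months, a ratio of 5.05. With length trends taken out it was 132 of 240 (55%), a ratio of 5.47, which argues against length likewise. Other differences shared by these libraries stay open. Genes are not independent, and the other genes were not matched for expression, so the exact p overstates the evidence.

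A passenger segment around the edited Rho gene from another strain could give changes near Rho that are not due to the mutation. Of the 200 tested genes nearest to Rho, 14 (7%) passed at 1 month against 5.06% of the others, a ratio of 1.38 (Fisher's exact p = 0.196). This lies between the bounds set for the test, so such a segment cannot be told apart from no segment. Gnb3 is among the 14.

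Loss of rods alone, with each rod's transcripts in the same proportions, would lower all rod-specific genes alike. At 6 months 9 such genes changed by between -2.58 (Rho) and -1.72 (Gngt1), and their heterogeneity per degree of freedom was 2.11, between the bounds of 2 and 3 set for the test. Loss of rods may therefore account for the rod list, and a change of transcripts within rods cannot be told apart from it.

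At 1 month, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The split by genotype gave 794 genes and the highest other 1143. That one, P23H replicates 1 and 2 and wildtype replicate 3 against the rest, points to a structure besides genotype. Library deviations from gene means were correlated with GC content across genes, which are not independent replicates. The correlations were -0.339, -0.277 and -0.217 in those 3 libraries and 0.11, 0.136 and 0.15 in the others. With each library's GC trend taken out the split gave 519 genes. GC content may account for part of it and cannot be told apart from other causes. Correlations with transcript length separated the same libraries, at -0.0658, 0.00439 and -0.0293 in those 3 and 0.172, 0.177 and 0.151 in the others. With length trends taken out the split gave 1418 genes, which argues against length as its whole cause. Lens tissue is argued against in the same way (1153 genes with a lens term). The split by genotype gave 959 genes with the GC trend taken out.

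The other comparisons of 3 libraries with 3 also have 10 splits, too few for a share under 0.05. Against the real 3924 and 7070 genes at 3 and 6 months the highest other gave 0. For age in wildtype, the real values 7, 353 and 0 stood against 0, 0 and 1, and in P23H 2024, 4529 and 490 against 0, 0 and 727, the last from a split that points to a structure of the 3- and 6-month P23H libraries. Over all ages, of 100 drawn splits that by genotype gave 7047 genes and the highest other 3924. This argues against chance, though draws that mix genotypes can have lower counts.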
